A study of Homo sapiens with 6 samples.

How the data were processed

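Messenger RNA levels were measured by RNA sequencing in HK2 cells, in 3 cisplatin libraries and 3 libraries with NSUN7 silencing plus cisplatin. Per the labels' protocols, RNA was extracted with Trizol and libraries were made from 1 ug of total RNA with an Illumina TruSeq kit. The deposited table gives raw counts per gene, per the file headers, for 16648 protein-coding genes in all 6 libraries. The authors' genome build was hg38, per the submitters' processing notes. The aligner, the counting tool, the annotation release, the strandedness, and the type and sequence of the silencing reagent are not given in the sources used here. How reads that match several genes were counted is not given either, so counts of genes with near-identical copies or overlapping neighbours are uncertain. The deposited table also gives values on a log2 scale, which the authors normalized with edgeR, per the file headers. The 1 such column used here, that of cisplatin replicate 1, differed by at most 0.000105 from log2 CPM recomputed from the counts with TMM factors and a prior count of 2. The other 5 normalized columns were not used, because their names do not set them apart from the count columns. The table held 2 emptied lines, and 14 symbols stood on 2 rows, of which the gene lists took the row with the higher mean. The table's biological process terms were not used, because 1287 cells were partly removed.

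Samples were grouped by their titles. The main test was edgeR 4.0.16 (quasi-likelihood fit and F test, group as the only term) in R 4.3.3, on the counts as deposited with TMM scaling and the default expression filter, which left 12781 genes. TMM factors lay between 0.994 and 1.01. Calls used Benjamini-Hochberg adjusted p under 0.05, and a second count also required an absolute log2 fold change of at least 1. Standard errors of log2 fold changes were derived from the fold change and its F statistic. Levels are CPM with TMM scaling. For NSUN7, SPARC and HMGB1, an exact two-sided permutation test of the CPM means was added, whose smallest possible p is 0.1. Gene lists were tested with camera (limma 3.58.1) with a preset inter-gene correlation of 0.01, adjusted over the 24 lists, and again with an estimated correlation. Replicate numbers appear in the titles of both groups, and nothing in the labels says that a number marks a shared culture or day, so the fit has no replicate term.

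The lists, the test, its design and the alternatives were fixed before the data were examined. The genes named were also fixed by rule. The rule took NSUN7, SPARC, HMGB1 and every m5C gene, and the 12 genes per direction with the largest absolute log2 fold change among called genes with a mean of at least 1 CPM, a gene symbol and no overlap between groups. It also took up to 4 members with the smallest p per list, and the 5 genes per direction with the smallest p. Some genes that the rule took are not reported here. Lists covered m5C writers, erasers and readers, the SPARC and HMGB1 axis, NF-kB inflammation, type I interferon response, p53 targets, necroptosis and pyroptosis, ferroptosis, tubular injury, proximal tubule function, cisplatin transport and repair, extracellular matrix, epithelial junctions, mitosis, DNA replication, cholesterol synthesis, the integrated stress response, endoplasmic reticulum chaperones, NRF2 targets, hypoxia and glycolysis, mitochondrial mRNAs, heat shock, immediate early genes, other cell types and histones.

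Totals of 25619146 to 33437100 counts per library set the precision. The procedure was tested on simulated counts for this comparison, drawn from the real means and library sizes, with 200 genes changed. Dispersions followed the trend with expression and not each gene's own value. Genes more variable than that trend were therefore not represented, and the rates below may be optimistic for them. Of 12711 simulated genes that entered the test, those changed 1.2-fold were called in 44.9% of cases, those changed 1.5-fold in 82%, 2-fold in 92% and 4-fold in 100%. Of 12488 unchanged simulated genes, 9 were called. Far fewer genes were changed here than the 5943 called in the real data. The adjusted p threshold therefore asked for a smaller unadjusted p in the simulation, and these rates are not those of the real test. A simulated list lowered by 0.2 on the log2 scale was called by camera (adjusted p = 2.24e-06), and 0 of 5 unchanged lists were. Simulated genes were drawn independently of each other, so these lists could not show false calls that come from correlated genes. A split of the real libraries that mixed the groups called 10 lists with the preset correlation, and 0 genes. Such a split keeps part of the group difference, so its list calls cannot be read as false calls alone. The rest of that difference adds to the spread, so the 0 genes were partly built in.

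Alternatives covered DESeq2 1.42.0, RLE size factors, library totals alone, no filter on low counts, a filter of 1 CPM in 3 libraries, the replicate number as a block, leaving out each library, camera with an estimated correlation, and fry. Added after the data were examined were limma-trend on log2 CPM, a correction for GC content and transcript length, the same with the replicate block, and leaving out genes with the words described next or genes with jumping counts. GENCODE release 29 (hg38) gave positions for 16643 genes, and lengths and GC content for 16525. The same release gave 3′ UTR sequences, the longest per gene, for a search of 7-base words in 9460 genes above a log2 CPM of 3 with a 3′ UTR of at least 50 bases. In that search, log2 changes were limited to an absolute value of 2 and adjusted for 3′ UTR length, GC content and expression (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3). A search with 20 planted words on shuffled values ranked 20 of them first. Figures were drawn with matplotlib 3.10.9.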

Results

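RNA from HK2 cells, an immortalized line of human kidney proximal tubule epithelium, was sequenced as 6 libraries in 2 groups. The cisplatin group comprised 3 libraries from cells given cisplatin, a platinum drug that binds DNA and injures tubule cells. The sample titles do not say whether these cells received a control reagent. If they did not, delivery of the silencing reagent differed between the groups along with NSUN7. The other group comprised 3 libraries from cisplatin-treated cells in which NSUN7, a member of the NOP2/Sun family of RNA 5-methylcytosine (m5C) methyltransferases, had been silenced. Total counts were 29132243, 31563593 and 29717445 in cisplatin replicates 1 to 3 and 25619146, 27921108 and 33437100 in the silenced replicates 1 to 3. Libraries of the same group differed by more than sampling noise (chi-square per degree of freedom from 3.41 to 5.31 over genes), and libraries of different groups differed more (25.8 to 31.7), so each library was counted as 1 replicate. The labels do not say that replicates came from separate cultures, so the p-values measure only the spread between these libraries, which may be technical. Libraries without cisplatin were not analysed here, and the effect of cisplatin itself was not measured.

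The first comparison addressed how far NSUN7 mRNA fell in the silenced cells. NSUN7 (ENSG00000179299, chromosome 4) had 296, 332 and 341 counts in the cisplatin libraries and 22, 23 and 36 counts in the silenced libraries. The level was 10.7 ± 0.716 CPM (counts scaled to library size; SD, n = 3) with cisplatin alone and 0.922 ± 0.135 CPM (SD, n = 3) with silencing. The silenced libraries therefore kept 8.61% ± 1.26 (SD, n = 3) of the cisplatin mean, with no overlap between groups. The log2 fold change was −3.52 ± 0.17 (SE), with a Benjamini-Hochberg adjusted p of 1.20e-11 in edgeR's quasi-likelihood test. A two-sided exact permutation test of 3 against 3 libraries gave p = 0.1, the smallest value that this design allows.

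SPARC and HMGB1 are the genes that the series title places downstream of NSUN7. SPARC, a secreted matricellular glycoprotein (ENSG00000113140, chromosome 5, bases 151661096 to 151687165 on the minus strand of hg38), fell from 1071 ± 17.2 CPM with cisplatin to 527 ± 3.66 CPM with silencing (SD, n = 3 each). The silenced libraries held 49.2% ± 0.342 (SD, n = 3) of the cisplatin mean, and the log2 fold change was −1.02 ± 0.03 (SE; edgeR quasi-likelihood adjusted p = 2.74e-15). Its p was the smallest among the 12781 genes tested. The 3′ untranslated region (UTR) of SPARC holds the 8-base word TTAATCAA at bases 151662602 to 151662609, and the NSUN7 coding sequence holds the same word. HMGB1 (ENSG00000189403), a nuclear protein that acts as an alarm signal when released, moved far less. Its level was 625 ± 15.3 CPM with cisplatin and 582 ± 25.5 CPM with silencing (SD, n = 3 each), with a log2 fold change of −0.10 ± 0.03 (SE; edgeR adjusted p = 0.0123). The HMGB1 groups overlapped, the two-sided exact permutation p was 0.2, and the edgeR call was lost without the silenced replicate 3 (log2 fold change −0.08, adjusted p = 0.101).

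**Figure D1:**
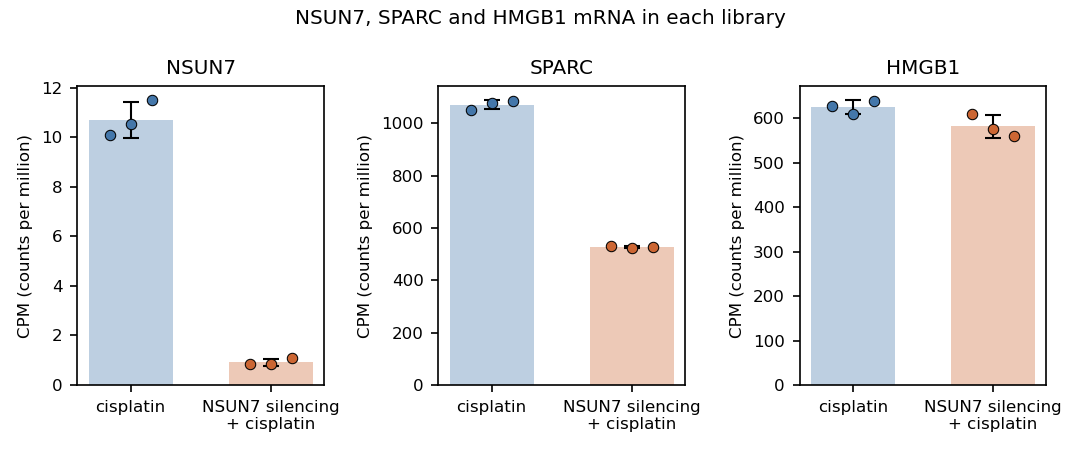
NSUN7, SPARC and HMGB1 mRNA in CPM (y axis, counts scaled to library size) in the cisplatin libraries and the libraries with NSUN7 silencing plus cisplatin. Bars are means, error bars are SD and points are the 3 libraries of each group; NSUN7 stood at 8.61% and SPARC at 49.2% of the cisplatin mean, and the HMGB1 groups overlapped.

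The main comparison addressed which mRNAs differed between cisplatin-treated cells with and without NSUN7 silencing. Of 12781 genes tested, 2994 rose and 2949 fell at an adjusted p under 0.05 in edgeR's quasi-likelihood test. Most of these changes were small: 85.5% of the called genes changed by less than 1.5-fold, and the median absolute log2 change was 0.26. At least 2-fold changes were called in 105 genes that rose and 169 that fell. After a correction for GC content and transcript length, which also re-centred each library, 3540 genes were higher and 2664 lower. The 2-fold counts moved with the filter on low counts, from 173 rises and 219 falls without a filter to 56 rises and 104 falls with at least 1 CPM in 3 libraries. The groups did not overlap in 54.4% of tested genes, against 10% expected by chance, and the biological coefficient of variation was 4.60%.

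The smallest p-values belonged to abundant genes. NT5E, the ectonucleotidase CD73 that makes adenosine, rose 2.27-fold (log2 fold change 1.18 ± 0.03 SE), and the cytokine gene IL11 rose 2.07-fold (1.05 ± 0.03). SMTN, which encodes smoothelin, rose by 0.99 ± 0.04, the deubiquitinase gene USP24 by 0.95 ± 0.04 and the AP-1 gene FOSB by 0.83 ± 0.03 on the log2 scale. Among the genes that fell, RPA1, the large subunit of the single-stranded DNA binding complex RPA, had a log2 fold change of −1.26 ± 0.04 and the matrix proteoglycan gene VCAN one of −1.05 ± 0.03. The 3′ UTR of RPA1 holds the word TTAATCAA 2 times. The lipid desaturase gene SCD (−0.79 ± 0.03) also fell. The adjusted p of each of these genes in edgeR's quasi-likelihood test was 2.73e-12 or smaller.

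Larger fold changes were found in genes of low abundance. Among called genes with a mean of at least 1 CPM and no overlap between groups, the largest falls after NSUN7 were in EPOP (−3.14 ± 0.52 SE), the tight junction gene OCLN (−2.54 ± 0.44), METTL7B (−2.14 ± 0.26), NEURL3 (−1.94 ± 0.39), the potassium channel gene KCNJ16 (−1.75 ± 0.28) and the epithelial trafficking gene RAB17 (−1.68 ± 0.21). GYG2, IFIT1, KLHDC7A, CBSL and ADAM22 fell by log2 fold changes between −1.65 and −1.55. Under the same limits, large rises were found in SMIM10L1 (3.94 ± 0.59 SE), RAP1GAP2 (2.51 ± 0.31), DHRS11 (1.92 ± 0.27), the potassium channel gene KCNQ3 (1.68 ± 0.30), NBPF14 (1.64 ± 0.19) and the TNF receptor adaptor gene TRAF1 (1.60 ± 0.21). ZNF251, PYGM, ANGPTL4, FAM209A and TMEM40 rose by log2 fold changes between 1.57 and 1.35. The largest edgeR adjusted p among these genes was 0.00366, for ZNF251. ZNF251 was no longer called without the silenced replicate 3 (log2 fold change 0.57, adjusted p = 0.121) or by DESeq2 (adjusted p = 0.0556), and the EPOP change shrank to −1.86 without cisplatin replicate 2. When 1 library was left out, the log2 fold change of NEURL3 ran from −2.78 to −1.55 and that of SMIM10L1 from 3.33 to 4.44. The 3′ UTRs of SMIM10L1 and KCNQ3, which rose, also hold the word TTAATCAA. The SMIM10L1 counts differed widely within the silenced group (29, 267 and 456), as did those of EPOP within the cisplatin group (281, 1184 and 137), and OCLN stood at 0.876 CPM in cisplatin replicate 3 against 3.51 and 3.64 CPM in the others. CBSL, NBPF14 and FAM209A have near-identical copies in the genome, so their counts are uncertain.

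**Figure D2:**
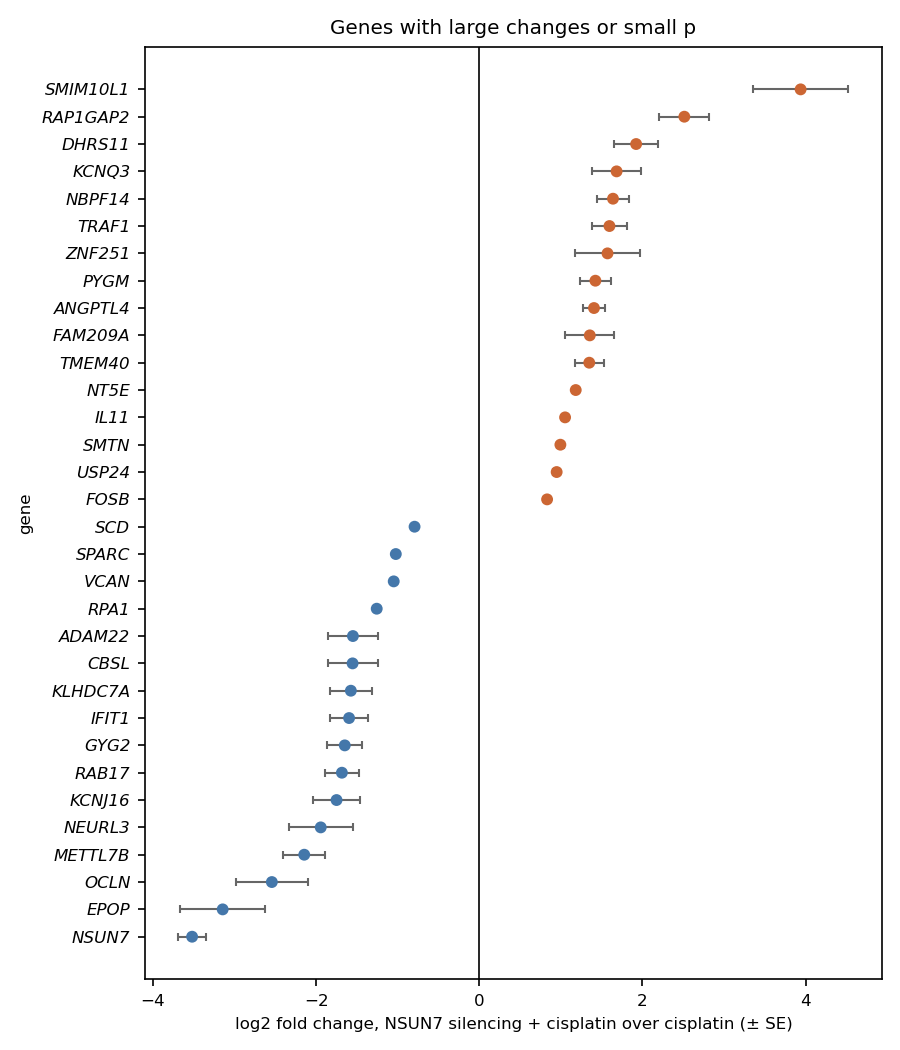
Log2 fold change (x axis, NSUN7 silencing plus cisplatin over cisplatin) of genes with large changes or small p and no overlap between groups (y axis). Points are edgeR estimates from 3 against 3 libraries and bars are SE, orange for rises and blue for falls; NSUN7 lies at −3.52, SPARC at −1.02 and NT5E at 1.18.

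Gene lists fixed before the data were examined were tested with camera, which compares a list with all other genes. Of 24 lists, 12 were called lower and 1 higher with the preset inter-gene correlation of 0.01. Calls held with an estimated correlation for 5 lists: immediate early genes, cholesterol synthesis, type I interferon response, endoplasmic reticulum chaperones and mitotic genes. Counts of members adjusted over the list alone equalled those over all genes tested unless given otherwise.

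Immediate early and AP-1 genes, which respond quickly to growth factor and stress signals, rose in 21 of 26 members and fell in 0 (median log2 fold change 0.41; camera adjusted p = 3.96e-17, and adjusted p = 0.0328 with an estimated correlation). The AP-1 genes FOSB (0.83 ± 0.03 SE) and FOSL1 (0.68 ± 0.04) rose, as did DUSP5 (0.78 ± 0.04) and DUSP1 (0.60 ± 0.03), which encode phosphatases of MAP kinases.

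Cholesterol synthesis genes fell in 19 of 24 members and rose in 1 (median −0.24; camera adjusted p = 5.62e-09, and adjusted p = 0.0328 with an estimated correlation). MSMO1 (−0.48 ± 0.04 SE), an enzyme of the late pathway, fell together with the sterol carrier gene STARD4 (−0.62 ± 0.04).

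Type I interferon response genes fell in 20 of 32 tested members and rose in 0 (median −0.40; camera adjusted p = 2.95e-07, and adjusted p = 0.0328 with an estimated correlation). PARP14 (−0.46 ± 0.03 SE), PARP9 (−0.60 ± 0.05) and the antiviral synthetase gene OAS3 (−0.39 ± 0.03) fell, and the low-abundance IFIT1 fell from 2.94 ± 0.406 to 0.969 ± 0.0110 CPM (SD, n = 3 each).

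Endoplasmic reticulum chaperone genes fell in 13 of 22 members and rose in 0 (median −0.20; camera adjusted p = 4.73e-06, and adjusted p = 0.0334 with an estimated correlation). The calreticulin gene CALR (−0.62 ± 0.03 SE), the protein disulfide isomerase genes PDIA4 (−0.53 ± 0.03) and PDIA3 (−0.33 ± 0.03), and HSP90B1 (−0.36 ± 0.03) fell. Mitotic genes fell in 21 of 32 members, or 23 adjusted over the list alone, and rose in 0 (median −0.16; camera adjusted p = 1.12e-05, and adjusted p = 0.0370 with an estimated correlation). The kinesin gene KIF20A (−0.48 ± 0.04), CCNB1 (−0.29 ± 0.03), HMMR (−0.29 ± 0.03) and CDK1 (−0.25 ± 0.03) fell. Genes of DNA replication and the G1/S transition moved both ways, with 9 of 36 higher (10 adjusted over the list alone) and 8 lower (camera adjusted p = 0.776). CCNE2 rose (0.29 ± 0.03), and PRIM1 (−0.41 ± 0.05), RFC3 (−0.33 ± 0.05) and PCNA (−0.26 ± 0.03) fell.

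The other 8 called lists lost their call with an estimated correlation. The estimate was above the preset 0.01 for extracellular matrix (0.0543), NRF2 targets (0.0941), tubular injury (0.154) and mitochondrial mRNAs (0.550). It was below 0.01 for the SPARC and HMGB1 axis (−0.0353), epithelial junctions (−0.00615), ferroptosis (−0.0391) and proximal tubule function (−0.0523). A higher correlation thus does not account for the loss in those lists. With an estimate, camera also takes its degrees of freedom from the 6 libraries and not from the number of genes, which raises p by itself. The interferon list, with an estimate of −0.0159, likewise moved from a camera adjusted p of 2.95e-07 to 0.0328. For the lists with a higher estimate, the effects of correlation and of degrees of freedom were not separated. Extracellular matrix and mesenchymal genes fell in 21 and rose in 9 of 43 tested members (camera adjusted p = 0.000415, and adjusted p = 0.147 with an estimated correlation). SPARC and the integrin gene ITGAV (−0.64 ± 0.03 SE) fell, and the integrin gene ITGA5 (0.54 ± 0.03) rose. Epithelial junction genes fell in 11 of 19 tested members and rose in 0 (camera adjusted p = 0.00133, and adjusted p = 0.0683 with an estimated correlation), with falls in EPCAM (−0.85 ± 0.06), JUP (−0.59 ± 0.05), F11R (−0.74 ± 0.09) and OCLN. The SPARC and HMGB1 axis list fell in 5 of 11 tested members, or 6 adjusted over the list alone, and rose in 1 (camera adjusted p = 0.000415, and adjusted p = 0.0652 with an estimated correlation). Besides SPARC and HMGB1, it held falls in HMGB3 (−0.26 ± 0.03), the pattern recognition receptor gene TLR2 (−0.63 ± 0.11) and its adaptor MYD88 (−0.20 ± 0.05). SPARC and HMGB1 are named in the series title, so their place on this list is not independent evidence of its direction.

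Tubular injury markers fell in 9 and rose in 4 of 21 tested members (camera adjusted p = 0.000218, and adjusted p = 0.177 with an estimated correlation). HAVCR1, which encodes kidney injury molecule KIM-1, fell by 0.68 ± 0.04 (SE) on the log2 scale, and LCN2, which encodes the injury marker NGAL, fell from 214 ± 6.39 to 131 ± 6.60 CPM (SD, n = 3 each). SPP1 fell (−0.66 ± 0.03 SE) and HBEGF, an epidermal growth factor receptor ligand, rose (0.52 ± 0.03). Proximal tubule function genes fell in 8 and rose in 1 of 11 tested members (camera adjusted p = 0.0347, adjusted p = 0.147 with an estimated correlation, and adjusted p = 0.155 without a filter on low counts). The brush border peptidase genes DPP4 (−0.86 ± 0.08) and MME (−0.52 ± 0.04) and the gamma-glutamyltransferase gene GGT1 (−0.27 ± 0.05) fell, and the transcription factor gene PAX8 rose (0.28 ± 0.04).

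Targets of the antioxidant regulator NRF2 fell in 16 of 24 tested members, or 17 adjusted over the list alone, and rose in 3 (camera adjusted p = 0.000126, and adjusted p = 0.147 with an estimated correlation). The glutathione reductase gene GSR (−0.89 ± 0.05 SE), the ferritin gene FTH1 (−0.44 ± 0.03) and PGD (−0.25 ± 0.03) fell, and OSGIN1 rose (0.56 ± 0.06). Ferroptosis genes fell in 9 and rose in 3 of 17 tested members (camera adjusted p = 0.0288, and adjusted p = 0.147 with an estimated correlation). The members that moved included the transferrin receptor gene TFRC (−0.61 ± 0.02), FTH1 and LPCAT3 (−0.38 ± 0.05), whereas SLC3A2, a subunit of the cystine transporter, rose (0.51 ± 0.03).

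Mitochondrially encoded mRNAs fell in 7 of 13 members and rose in 0 (median −0.09; camera adjusted p = 0.0460, and adjusted p = 0.656 with an estimated correlation). MT-CO3 (−0.21 ± 0.02 SE), MT-ND5 (−0.20 ± 0.03), MT-CO2 (−0.14 ± 0.03) and MT-ATP6 (−0.13 ± 0.03) fell. They took 6.67% to 6.89% of counts in the cisplatin libraries and 6.20% to 6.59% in the silenced libraries. This list was not called without cisplatin replicate 1 (adjusted p = 0.0594) or 2 (0.0586), or without the silenced replicate 1 (0.101) or 3 (0.139). Replication-dependent histone mRNAs were listed as a check of RNA selection, because mRNAs of this class typically lack a poly(A) tail. Whether the members counted here lacked one was not tested. The list fell in 8 and rose in 1 of 14 tested members (median −0.29, camera adjusted p = 0.0531, and adjusted p = 0.167 with an estimated correlation). The histone call depended on the setting: adjusted p was 0.0467 with the replicate number as a block, 0.00785 with limma-trend and 0.0381 with the correction for GC content and length, but 0.0577 with DESeq2, 0.0691 with the stricter filter and 0.0502 to 0.131 when 1 library was left out. HIST2H2BE (−0.56 ± 0.09), HIST1H2AC (−0.56 ± 0.10), HIST1H3H (−0.53 ± 0.13) and HIST1H2BD (−0.35 ± 0.07) were among the falls, and histone genes have near-identical copies.

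NF-kB inflammatory genes moved both ways, with 9 of 23 tested members higher (10 adjusted over the list alone) and 8 lower (camera adjusted p = 0.765). IL6 rose from 227 ± 2.99 to 368 ± 4.90 CPM and CXCL8, a neutrophil chemokine gene, from 1917 ± 85.6 to 2460 ± 62.5 CPM (SD, n = 3 each). The complement gene C3 fell from 186 ± 4.75 to 109 ± 2.88 CPM (SD, n = 3 each), and SOD2 fell by 0.39 ± 0.03 SE on the log2 scale. Necroptosis, pyroptosis and inflammasome genes were called in 3 of 13 tested members (camera adjusted p = 0.730), with 1 rise and with falls in NINJ1 (−0.82 ± 0.07) and IL18 (−0.48 ± 0.05). Targets of p53 were divided between 9 rises and 8 falls among 27 tested members (camera adjusted p = 0.122), with rises in PMAIP1 (0.47 ± 0.03), AEN (0.76 ± 0.05), GADD45A (0.45 ± 0.03) and BTG2 (0.57 ± 0.05).

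Genes of cisplatin transport and platinum-DNA repair rose in 7 and fell in 8 of 31 tested members (camera adjusted p = 0.730). The efflux transporter genes ABCB1 (−0.51 ± 0.03 SE) and ATP7B (−0.86 ± 0.13) fell, and FANCA (0.50 ± 0.04) and REV3L (0.27 ± 0.04), genes of crosslink repair and translesion synthesis, rose. Hypoxia and glycolysis genes rose in 7 and fell in 9 of 31 tested members (camera adjusted p = 0.730), with a rise in ADM (0.52 ± 0.04) and falls in LDHA (−0.31 ± 0.03), P4HA1 (−0.43 ± 0.03) and P4HA2 (−0.45 ± 0.04). ATF4 targets of the integrated stress response rose in 7 and fell in 9 of 29 tested members (camera adjusted p = 0.776), with a rise in SLC3A2 and falls in VLDLR (−0.58 ± 0.05), PHGDH (−0.37 ± 0.04) and MTHFD2 (−0.24 ± 0.03). Heat shock genes rose in 7 and fell in 2 of 13 tested members (camera adjusted p = 0.314), with rises in HSPA8 (0.27 ± 0.03), HSP90AA1 (0.19 ± 0.02) and BAG3 (0.23 ± 0.04) and a fall in CRYAB (−0.72 ± 0.07).

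Other m5C writers, erasers and readers moved less than NSUN7. Of 16 tested members, 5 rose and 3 fell, NSUN7 included (camera adjusted p = 0.765). The m5C methyltransferase gene NSUN2 (0.22 ± 0.03 SE), the reader gene YBX1 (0.19 ± 0.03), the dioxygenase gene TET3 (0.53 ± 0.05), SRSF2 (0.10 ± 0.03) and NSUN5 (0.17 ± 0.06) rose. YBX2 fell (−0.32 ± 0.08), and TET1 fell (−1.21 ± 0.40) at mean levels under 1 CPM in both groups. Calls were lost for TET1 without cisplatin replicate 2 or 3 or the silenced replicate 2 or 3 (adjusted p from 0.0580 to 0.0923), for NSUN5 without any of the same 4 libraries (0.0503 to 0.105), and for SRSF2 without the silenced replicate 1 (0.0505). NOP2 (0.32 ± 0.21), ALKBH1 (0.11 ± 0.08), NSUN3 (−0.14 ± 0.10), NSUN4 (0.05 ± 0.05), TRDMT1 (−0.14 ± 0.22), TET2 (0.04 ± 0.13), NSUN6 (0.02 ± 0.12) and ALYREF (0.00262 ± 0.0418) did not pass the edgeR test. Markers of other kidney and blood cell types were near the detection limit. Of 21 in the table, 8 were tested and 1 was called lower, 0 adjusted over the list alone (camera adjusted p = 0.765). The called member, the pericyte marker RGS5, stood at 2.29 ± 0.394 CPM with cisplatin and 1.45 ± 0.307 CPM with silencing (SD, n = 3 each) and was not called without cisplatin replicate 2 or 3 or the silenced replicate 1 or 3 (adjusted p from 0.0631 to 0.134). CDH5 (0.77 ± 0.45 SE) and CD14 (−0.26 ± 0.27) did not pass the edgeR test. HBB (−1.55 ± 0.67) did not pass it either (adjusted p = 0.0641) but was called with the replicate number as a block (0.0401), without a filter on low counts (0.00498), by limma-trend (0.0111) and without the silenced replicate 2 (−4.72, adjusted p = 6.66e-05), and its log2 fold change ran from −4.72 to −0.94 when 1 library was left out.

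**Figure D3:**
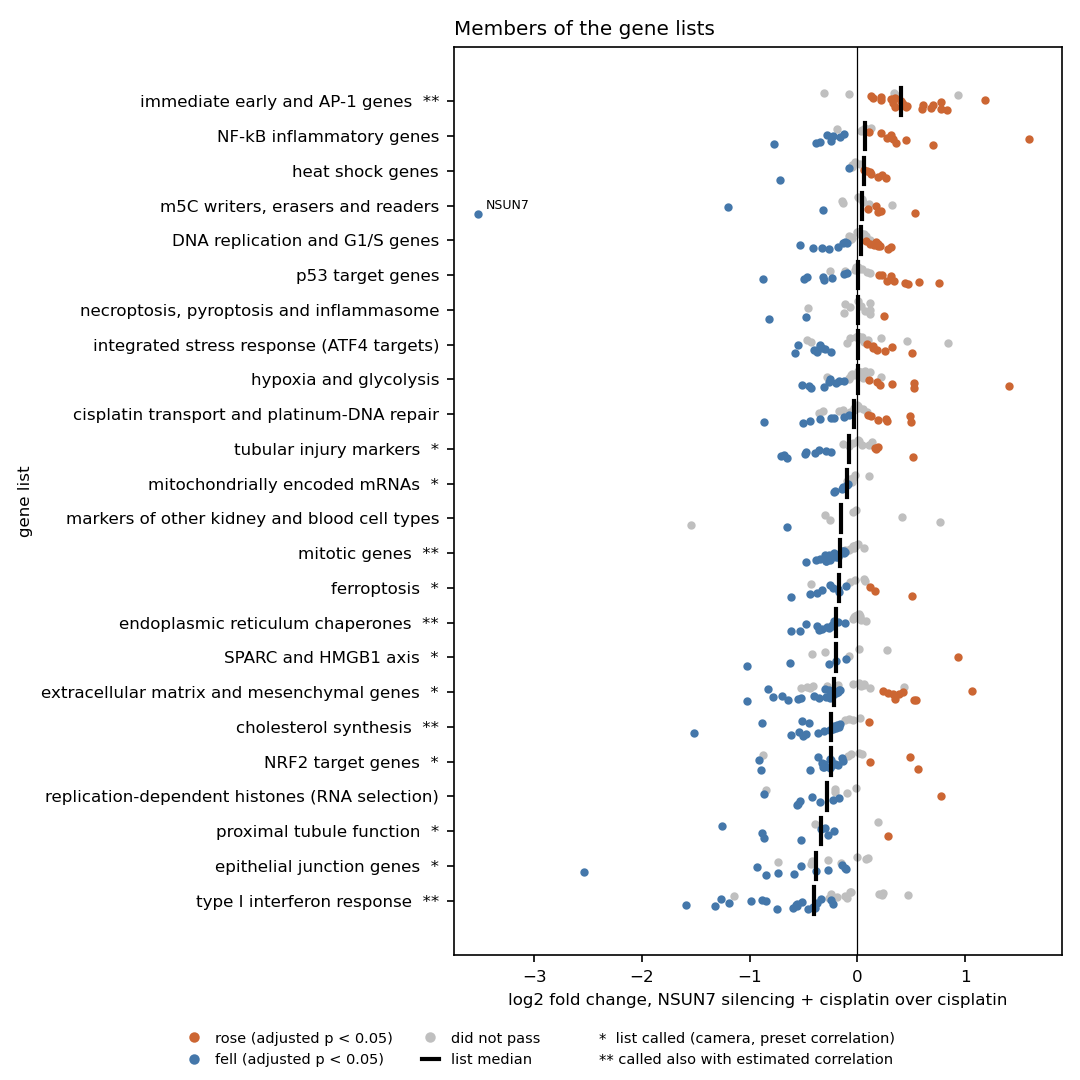
Log2 fold change of every tested member (x axis, NSUN7 silencing plus cisplatin over cisplatin) of the 24 gene lists (y axis, ordered by median). Points are genes (orange, rose; blue, fell; grey, did not pass adjusted p 0.05), black bars are list medians, 1 asterisk marks lists called by camera with the preset correlation and 2 asterisks those also called with an estimated correlation; the medians run from −0.40 for the interferon list to 0.41 for the immediate early list.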

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

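Settings chosen after the data were examined were limma-trend, the GC and length correction with or without the replicate block, and leaving out genes with the TTAATCAA words or with jumping counts. Called genes numbered from 5140 to 6204 over the alternatives other than leaving out word genes (4667 of 10418 tested), against 5943, and calls shared with the main test kept their direction, apart from 1 gene in 1 alternative. The balance shifted with the GC and length correction to 3540 genes higher and 2664 lower (3538 and 2637 with the replicate block). That correction also re-centred each library, and the median log2 change of tested genes moved from −0.000765 to 0.0246. The shift in balance can therefore not be read as GC or length bias alone. Leaving out 1 library gave 2603 to 2762 genes higher and 2537 to 2696 lower. Rises of at least 2-fold numbered 173 without a filter on low counts, where more genes were tested, and 56 with 1 CPM in 3 libraries, where 104 falls were left and fewer genes were tested. NSUN7 stayed called under every alternative. With an estimated correlation, camera called 4 lists lower, and adjusted p rose to 0.0652 for the SPARC and HMGB1 axis, 0.0683 for epithelial junctions, 0.147 for ferroptosis, proximal tubule function, extracellular matrix and NRF2 targets, 0.177 for tubular injury and 0.656 for mitochondrial mRNAs. Fry, which does not compare a list with other genes, called 4 lists higher: immediate early genes, m5C genes (adjusted p = 0.0118), p53 targets (0.000850) and heat shock (0.00635). It also called hypoxia lower (0.0118), and mitochondrial mRNAs were not called (0.0601). Proximal tubule function had an adjusted p of 0.155 without a filter, mitochondrial mRNAs had 0.0526 with the stricter filter and from 0.00223 to 0.139 when 1 library was left out, and under limma-trend ferroptosis had 0.0620 and tubular injury 0.0954. Leaving out genes with the TTAATCAA words, SPARC among them, gave 0.307 for the SPARC and HMGB1 axis, 0.281 for ferroptosis and 0.145 for proximal tubule function and for extracellular matrix, with fewer members tested. Histones passed with 0.0467 (replicate block), 0.000230 (fry), 0.00785 (limma-trend), 0.0381 (GC and length), 0.0288 (GC and length with the block), 0.0445 (without word genes) and 0.0457 (without jumping genes), but not with an estimated correlation (0.167), DESeq2 (0.0577), the stricter filter (0.0691) or 1 library left out (0.0502 to 0.131). Directions of uncalled lists turned for the integrated stress response with the GC and length correction (0.954) and without word genes (0.919), and for m5C genes without word genes (0.758). Uncalled named genes turned sign for ALYREF with library totals alone (−0.00306) and without word genes (−0.000916). When 1 library was left out, log2 changes ran from −0.0301 to 0.0206 for ALYREF, −0.0776 to 0.154 for TET2, −0.0437 to 0.0846 for NSUN6, −0.456 to 0.0480 for CD14 and −0.384 to 0.0120 for TRDMT1. Except where the number of genes tested differed, the cause was not tested. Same-numbered libraries of the groups deviated together weakly at most (r of 0.0428, −0.00414 and 0.0489 across genes). Libraries of different numbers had r from −0.0700 to 0.0298. The highest r was of a same-numbered pair, but all were small, so numbers were not taken to pair libraries. With the replicate block, 2983 genes were higher and 2948 lower. The planned pseudocount does not apply to counts, and the test on the deposited normalized values was not run because 5 of their 6 columns were not used. With 22 to 36 counts in the silenced libraries, depth limits how precisely the residual NSUN7 level is known.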

Other observations

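The term tests, the word search, the GC and length correction, the test of closeness in the genome, the comparison with other words of the same letters, and the explanations by reagent pairing and by loss of NSUN7 were chosen only after results were seen. Among 828 annotation terms tested with camera, 113 were called with the preset correlation and 0 with an estimated correlation (smallest adjusted p = 0.414). With an estimate, the few degrees of freedom of 6 libraries limit how small a camera p can become. Even the immediate early list moved from an unadjusted camera p of 1.65e-18 to 0.00206. The 0 calls among 828 terms were therefore largely built in and do not show that correlated genes account for the 113. Genes of the small-subunit processome, which assembles the small ribosomal subunit in the nucleolus, rose in 27 and fell in 1 of 32 tested members (median log2 fold change 0.32, camera adjusted p = 4.19e-12 preset, and adjusted p = 0.414 with an estimated correlation). Ribosome biogenesis genes rose in 47 and fell in 3 of 71. The translation initiation factor complex eIF3 rose in 13 of 16 members (median 0.18). Genes of the lysosomal lumen fell in 38 and rose in 5 of 61, and genes of the endoplasmic reticulum lumen fell in 73 and rose in 10 of 130 (median −0.21; adjusted p = 2.70e-07 preset, and adjusted p = 0.414 with an estimated correlation).

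Genes whose 3′ UTR holds the word TTAATCAA stood lower in the silenced cells: over 410 such genes the mean adjusted log2 change was −0.111 ± 0.0141 (SE across genes), and 42.0% of them fell and 19.3% rose, against 24.0% and 29.2% of 7539 genes with neither TTAATCAA nor its 7-base parts. TTAATCAA ranked 1 of 280 words made of the same letters (t = −9.504, against −5.377 for the next and −4.125 for the third), but it was picked from the same search, so this rank leaves base composition open. The median t was −0.033 over the 272 of these words that share no 6 bases with TTAATCAA. The log2 changes had first been adjusted for 3′ UTR length and GC content, so such a median was largely built in. It therefore leaves base composition and length open. A drop in 1 silenced library alone is argued against by means of −0.115, −0.110 and −0.105 in the 3 silenced libraries, each against the same cisplatin mean. Each cisplatin library against the other 2 gave −0.0061, 0.0005 and 0.0056. A candidate explanation is seed-like pairing of the silencing reagent with other mRNAs: of 15576 words of 7 bases, TAATCAA (t = −8.577) and TTAATCA (t = −8.566) were the most negative, against a largest absolute t of 5.497 in 100 shuffles, and NSUN7 holds TTAATCAA 1 time, in its coding sequence (chromosome 4, bases 40750892 to 40750899 of hg38, exon 2 of 11), as do 1.502% of genes with a coding sequence of like length. For sites in the coding sequence alone, the rule written before that test counted any mean that was not negative against reagent pairing. The mean was 0.0133 ± 0.0218 SE, which that rule counts against pairing at such sites. Its SE exceeds it, so the value cannot decide whether pairing acts at such sites. The comparison of 2 or more sites with 1 (difference −0.11 ± 0.0781 SE) left reagent pairing open. Loss of NSUN7 itself (mean −0.111) cannot be told apart from reagent pairing, because the groups hold no second reagent and no rescue.

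The excess of lowered genes with these words came to 151.5 of the 2424 lowered genes searched, or 6.25%. This excess was not adjusted for 3′ UTR length, GC content or expression, and the word was picked from the same data. The word lies in the last exon of SPARC (chromosome 5, bases 151662602 to 151662609 of hg38, exon 10 of 10, transcript base 2188 of 3701), and which 3′ ends of SPARC these cells use was not measured. Of the 20 lowered genes with the smallest p among those searched, 6 held TTAATCAA in the 3′ UTR, against 4.33% of all genes searched. At the other end of the search, 3596 genes with TATTTAT, the core of AU-rich elements, had a mean adjusted log2 change of 0.0376 (t = 6.012, also beyond the 5.497 of the shuffles, in the other direction).

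Calls covered 46.5% of tested genes, most of them small. A bias by GC content or transcript length is argued against as the whole cause, because 6204 genes were called after its removal, 5620 of them shared with the 5943 first called. A difference in library size is argued against by 5823 calls after every library was thinned to 25619146 counts. The 3 against 3 design allows 10 splits, too few for a share under 0.05: 1 of 10 splits, the real one, gave as many called genes (5943, highest other 0) and as many of at least 2-fold (274, highest other 0), and 1 of 10 gave as many gene lists with the preset correlation (13, highest other 10). With an estimated correlation the real split called 5 lists and the others 0. The other splits mix the groups, which adds the group difference to their spread, so low counts in them were partly built in. A biological effect of the silencing and any difference in handling that followed the groups stay open and untested.

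Counts of 28 genes differed at least 5-fold between libraries of one group, with at least 100 counts in 1 of them, and 16 of these genes were called in the main test. The gene VASN had 51, 40 and 47 counts in the cisplatin libraries and 701, 47 and 44 in the silenced ones, TCF20 had 724 counts in 1 silenced library and at most 89 in the others, and KANSL1 had 315 counts in cisplatin replicate 1 and at most 31 elsewhere; these examples were chosen after their values were seen. Counting noise at the dispersion typical of a gene's level is argued against, since counts simulated with that dispersion gave 0 such genes. The larger dispersion of these genes themselves was not simulated. Exon overlap with another annotated gene stays open (39.3% of these genes against 49.2% of others; odds ratio 0.669, 95% interval 0.283 to 1.52, Fisher's exact p = 0.346). Some of these genes lay close to each other, with 6 pairs within 500 kb against a median of 0 in 10000 random draws (share with as many pairs 2e-04). The pairs were among GSDMD, NAPRT and ZNF623, and between LENG8 and MBOAT7, NMRAL1 and VASN, and EPOP and PSMB3. The remaining genes, TCF20 and KANSL1 among them, had no partner within that distance. Reads split between copies of a region in the authors' reference, for example alternate versions of a locus, may account for the paired genes. No biological explanation was tested.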
